A study of Gallus gallus with 15 samples.

How the data were processed

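Gene expression was measured in the ileum of chickens with a NimbleGen oligonucleotide array, from total RNA, in 9 samples: product 1, product 2 and water on days 1, 7 and 15. Days 7 and 15 had 2 arrays a sample (a first run and a repeat run) and day 1 had 1, so there were 15 arrays. The labels name the dye cy5, and the labelling was done by the array's maker. The labels do not say whether the repeat arrays came from other birds, so they were taken as repeats of the sample. The p values within a day then measure only the spread between arrays, which may be technical.

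The authors deposited an intensity for each transcript, an RMA value on a linear scale, per the submitters' processing notes, which give no version. Each of the 55365 transcripts was read by up to 3 probes (3 for 55309) in 2 blocks of the array, and the deposited average of the 2 blocks was used. The deposited series table held 55315 of the transcripts with identical values. The genome build, annotation release and background step are not given in the sources used here, and probe sequences were not analysed here. Symbols came from matching RefSeq accessions to a RefSeq gene table (3827 transcripts) or from the array files alone (344); 4110 transcripts, 7.42%, had a symbol, with 4041 different symbols.

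Intensities were put on the log2 scale and quantile normalised between the 15 arrays, which moved array medians by at most 0.0361. The planned filter on dim transcripts needed single control probes or detection calls, which the files used here did not give, so it fell back to no filter, and the alternative without a filter equals the reported values. A transcript at or under 2 times the random-probe value (5.67 to 5.95 on the log2 scale) on every array of a group was taken as background there, and a difference from it is given as a lower bound. For arrays the number of arrays limits the precision.

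Differences were tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over 55365 transcripts within a comparison and a threshold of 0.05. Days were compared on the 9 first-run arrays with day and treatment as terms. Treatments over all days were compared on the 9 samples, with repeat arrays averaged and day as a term. Treatments on days 7 and 15, and the change of each product's difference from water between those days, were compared on 12 arrays in 6 groups of 2. In the repeat run each treatment had its own slide, which held its day 7 and day 15 arrays. In the first run only product 2 and water of day 15 shared a slide within a day. Treatments within a day were thus compared mostly between slides. Day 1 alone had 1 array a treatment and no test. The comparisons of both products with water on a day share the water arrays.

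The lists of genes, 31 in number with 449 genes measured, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera sets a list against all other transcripts, most without a symbol, so a shift of named genes as a class can enter its calls. Counts called in a list are to be read beside the share called among all 4110 transcripts with a symbol. Named genes were the 10 largest rises and 10 largest falls among called transcripts with a symbol and 1 sign in every matched pair of samples or arrays, and up to 4 called members of each list. For a list with none called, the members with the largest change are given as values. A gene with several transcripts is given by the brightest. Some genes that met this rule are withheld and not reported here, and the list counts include them.

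The alternatives were the values as deposited, median centring, cyclic loess, the mean log2 of the 2 blocks, the series table, stricter filters, limma with trend and robust variance, a 2-fold minimum, the run or the slide as a block, other sets of arrays, and leaving out each array or sample in turn. Cyclic loess, the block mean, the filter at 2 times the random-probe value, leaving out the 3 product 1 arrays, and the list tests with a run block or a left-out array were chosen after seeing the data. The fits were tested on simulated data with known changes. In the fit of days, 34% of changes of 2 on the log2 scale and 94% of changes of 4 were recovered, and 2 of 100 calls were false. For day 7 these were 48% and 96%, with 6 of 124 calls false. For the change between days they were 14% and 70%, with 5 of 73 false. These false calls were counted in simulated data only. With 1 sample per treatment and day, neither of these fits can estimate the spread between samples. How many of their real calls are false for treatment is therefore not shown by these counts. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.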

Results

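The ileum, the last stretch of the small intestine, was taken from chickens given product 1, product 2 or water, and its RNA was measured on an array that covers known and predicted chicken genes. The labels state that the birds were inoculated. What the products contain, how many birds gave each sample and how the birds were kept are not given in the sources used here. Samples were collected at day 1, day 7 and day 15, and the labels use the same number for the time after inoculation and for the developmental stage, so age and time since inoculation are 1 variable in this design. There was 1 sample for each treatment on each day, 9 in all. The 6 samples of days 7 and 15 were measured on 2 arrays each (a first run and a repeat run) and the 3 samples of day 1 on 1 array each, which makes 15 arrays.

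Each array gave an intensity for 55365 transcripts, of which 4190 came from RefSeq, 19143 from Ensembl and 32032 from gene prediction; 4110 carried a gene symbol, and only those are named here. Between 54.7% and 61.5% of the transcripts on an array lay above 2 times the value of its random probes. Means below are on the log2 scale with the SD and the number of samples or arrays, differences are log2 differences with their SE, and adjusted p values come from limma. The number of arrays limits the precision: on days 7 and 15 the p values measure the spread between the 2 arrays of a sample and not the spread between birds.

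The comparison of day 7 with day 1 asks how the ileum changed over the first week, with the 3 treatments as the 3 samples of each day. Genes of T cells, B cells, macrophages and antibody transport rose, with the counts in the next paragraph. JCHAIN, the chain that joins IgA and IgM into polymers, rose from 6.48 (SD 1.21, n = 3 samples) to 13.74 (SD 0.19, n = 3), a difference of 7.26 ± 0.43 (adjusted p = 1.3e-05), and PIGR, the receptor that carries those polymers across the epithelium, rose by 3.01 ± 0.43. GZMA, a granule protease of cytotoxic lymphocytes, rose from 9.61 (SD 0.67, n = 3) to 14.29 (SD 0.08, n = 3), and XCR1, a chemokine receptor of dendritic cells, rose by 4.14 ± 0.36. AvBD10, an avian beta-defensin, fell from 10.94 (SD 0.65, n = 3) to 6.39 (SD 1.42, n = 3). On day 7 it stood at 8.04 with product 1, and at 5.58 and 5.57 with product 2 and water. Those 2 values lay under the background limits of 5.67 to 5.95, so the size of the fall is uncertain and differed between treatments. Other large falls were those of HAND1, a transcription factor of the gut mesenchyme (-2.57 ± 0.46) and CRMP1, a protein of growing axons (-2.27 ± 0.31).

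By gene list, 15 of 21 measured T and cytotoxic cell genes rose and 0 fell on day 7, or 19 adjusted over the list alone, with a list median of 1.92 (SD 0.89 across genes). They included CTLA4 (2.43 ± 0.32), an inhibitory receptor of T cells, and XCL1 (2.33 ± 0.41), the ligand of XCR1. The limma camera test of this list gave an adjusted p of 3.84e-25, and adjusted p = 0.0706 with an estimated correlation. Of 19 B and plasma cell genes 6 rose, or 10 adjusted over the list alone, among them POU2AF1, a B cell coactivator (by at least 2.40, since day 1 lay at background); the list's adjusted p was 9.36e-09, and adjusted p = 0.0561 with an estimated correlation. Among macrophage and dendritic cell genes 4 of 12 rose, or 7 adjusted over the list alone, with CCR2 (2.41 ± 0.34) and CYBB (2.21 ± 0.32), a subunit of the phagocyte oxidase, beside XCR1. Camera for macrophages gave an adjusted p of 9.36e-09, and adjusted p = 0.0561 with an estimated correlation. Of 8 genes of antigen presentation 3 rose over all genes and over the list alone, DMA (2.93 ± 0.33), CD74 (2.30 ± 0.32) and BLB1 (1.57 ± 0.32), which load and present peptides on MHC class II (camera adjusted p 0.00192, and adjusted p = 0.104 with an estimated correlation). In the list of cytokines, chemokines and mediators 3 of 29 rose, or 6 adjusted over the list alone: CCL1 (2.64 ± 0.43), CCL5 (2.32 ± 0.36) and TNFSF15 (1.85 ± 0.30). That list's camera adjusted p was 1.58e-06, and adjusted p = 0.104 with an estimated correlation. The short list of immunoglobulin and IgA transport, 3 genes including JCHAIN and PIGR, gave 2 rises, or 3 adjusted over the list alone, at an adjusted p of 4.68e-07, and adjusted p = 0.0561 with an estimated correlation. JCHAIN is also a member of the B and plasma cell list, so both lists share its rise. Not every immune list moved this way: heterophil genes (14 genes, median -0.21) and interferon response genes (12 genes, median -0.40) had 0 calls over all genes or over the list alone, with camera adjusted p values of 0.449 and 0.399.

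Genes of the enteric nervous system fell in the same week: 5 of 19 fell and 0 rose, or 8 adjusted over the list alone. ELAVL4, an RNA-binding protein of neurons, fell from 11.99 (SD 0.14, n = 3) to 9.65 (SD 0.09, n = 3), SOX10, a glial transcription factor, changed by -2.07 ± 0.31, and NEFM, a neurofilament, by -2.11 ± 0.29. Camera for enteric neurons gave an adjusted p of 5.05e-07, and adjusted p = 0.0706 with an estimated correlation. Of 20 extracellular matrix genes 1 fell, COL14A1 (-2.05 ± 0.34), a collagen, or 3 adjusted over the list alone. Camera for matrix genes gave an adjusted p of 0.00192, and adjusted p = 0.297 with an estimated correlation. Haemoglobin genes rose: of 14 red blood cell genes 4 rose, over all genes and over the list alone, with HBAD at 2.35 ± 0.41 and HBBA at 1.81 ± 0.30. Camera for red blood cell genes gave an adjusted p of 0.0179, and adjusted p = 0.404 with an estimated correlation. Single rises were seen for NPAS2, a clock transcription factor (1.71 ± 0.35), and for AMY1A, an amylase (1.72 ± 0.32), from a pancreas list of 9 with 2 rises adjusted over the list alone and an adjusted p of 0.0273, and adjusted p = 0.297 with an estimated correlation. CD36, a fatty acid receptor, fell (-1.76 ± 0.36), as did GSTA3, a glutathione transferase (-1.48 ± 0.32). The 32 proliferation genes had a median of -0.44 (SD 0.40) with 0 calls over all genes or over the list alone, and the list's adjusted p was 1.02e-05, and adjusted p = 0.404 with an estimated correlation. The smooth muscle list (15 genes, median -0.24, 0 calls over all genes and 2 falls adjusted over the list alone) and the cholesterol synthesis list (11 genes, median 0.39, 0 calls either way) passed camera at adjusted p values of 0.0313 and 0.0254. Those became adjusted p = 0.414 with an estimated correlation and adjusted p = 0.633 with an estimated correlation.

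In total 686 transcripts rose and 552 fell, of which 102 and 67 had a symbol. The total of 1238 dropped to 174 without the water array of day 1 and to 220 without the first water array of day 7. It stood at 468 and 428 without the product 1 and product 2 arrays of day 1 and at 507 without that of product 2 on day 7. Without the 3 product 1 arrays it was 760. Of the 43 genes that the naming rule took as called, 12 stayed past the threshold whichever array was left out. Among them were JCHAIN, GZMA, XCR1, PIGR, CTLA4, AvBD10, ELAVL4 and CRMP1.

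**Figure D1:**
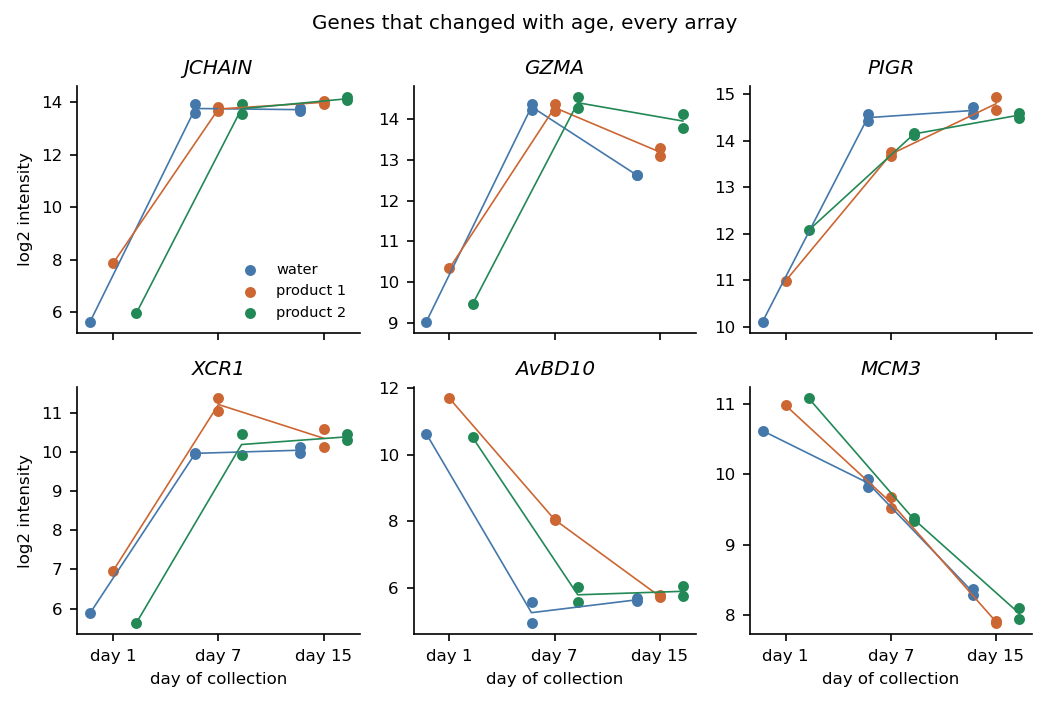
Log2 intensity (vertical axis) of 6 genes by day (horizontal axis), with each point 1 array, colours for water, product 1 and product 2, and lines joining sample means. JCHAIN, GZMA, PIGR and XCR1 stood higher on days 7 and 15 than on day 1 in all 3 treatments, and AvBD10 and MCM3 stood lower on day 15 than on day 1.

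Between day 1 and day 15 genes of T cells, B cells and macrophages rose, and genes of cell division and the interferon response fell, with the counts below. JCHAIN reached 13.93 (SD 0.24, n = 3 samples), a rise of 7.45 ± 0.43 over day 1 (adjusted p = 7.9e-06), PIGR rose by 3.65 ± 0.43, XCR1 by 4.01 ± 0.36 and GZMA by 3.68 ± 0.38. HSPB9, a small heat shock protein, rose from 9.92 (SD 0.97, n = 3) to 15.03 (SD 0.29, n = 3). AvBD10 fell from 10.94 (SD 0.65, n = 3) to 5.71 (SD 0.10, n = 3), within the background limits of 5.67 to 5.95, so the size is uncertain. AVD, the biotin-binding protein avidin (-3.37 ± 0.39), SPP1, the matrix protein osteopontin (-2.94 ± 0.46), and MCM3, a subunit of the DNA replication helicase (-2.81 ± 0.31), fell as well. MST1, a secreted growth factor (3.43 ± 0.47), and BMF, a promoter of apoptosis (3.31 ± 0.36), rose.

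Of the 32 proliferation genes 15 fell and 0 rose on day 15, or 25 adjusted over the list alone, with a median of -1.24 (SD 0.54). CENPF, a kinetochore protein (-2.25 ± 0.36), RFC3, a replication clamp loader (-1.89 ± 0.38), and CDC20, a mitotic activator (-1.69 ± 0.36), were among them. Camera gave this list an adjusted p of 2.7e-19, and adjusted p = 0.143 with an estimated correlation. In the T and cytotoxic cell list 12 of 21 rose and 0 fell, or 15 adjusted over the list alone, with CD8A (2.17 ± 0.41), a coreceptor of cytotoxic T cells, and PTPRC (2.02 ± 0.35), the pan-leukocyte phosphatase. Camera for T cells gave an adjusted p of 1.87e-15, and adjusted p = 0.143 with an estimated correlation. B and plasma cell genes rose in 5 of 19, or 7 adjusted over the list alone, with IRF4 (1.99 ± 0.37), a regulator of plasma cells. Camera for B cells gave an adjusted p of 7.36e-05, and adjusted p = 0.131 with an estimated correlation. Macrophage and dendritic cell genes rose in 3 of 12, or 5 adjusted over the list alone (adjusted p 1.44e-05, and adjusted p = 0.131 with an estimated correlation), and antigen presentation genes in 3 of 8 over all genes and over the list alone, led by DMA at 2.77 ± 0.33. Camera for antigen presentation gave an adjusted p of 0.00413, and adjusted p = 0.143 with an estimated correlation. The immunoglobulin and IgA transport list had 2 rises among 3 genes over all genes and over the list alone. Camera for IgA transport gave an adjusted p of 2.97e-05, and adjusted p = 0.131 with an estimated correlation.

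The interferon response moved the other way: 3 of 12 fell and 0 rose over all genes, and 4 fell and 1 rose adjusted over the list alone. IFI27L2 (-1.73 ± 0.34), the antiviral GTPase gene MX1 (-1.63 ± 0.38) and the antiviral synthetase-like gene OASL (-1.28 ± 0.30) fell (list adjusted p 0.0371, and adjusted p = 0.377 with an estimated correlation). Cytokines and mediators had 4 rises and 1 fall among 29, or 6 and 2 adjusted over the list alone, with TNFSF15 up by 2.06 ± 0.30 and IL1RL1, a receptor of interleukin 33, at -1.65 ± 0.32. Camera for cytokine genes gave an adjusted p of 0.00216, and adjusted p = 0.28 with an estimated correlation. Enteric neuron and glia genes fell in 6 of 19, or 8 adjusted over the list alone, ELAVL4 at -2.23 ± 0.30. Camera for enteric neurons gave an adjusted p of 0.00162, and adjusted p = 0.176 with an estimated correlation. Matrix genes gave 2 falls and 1 rise among 20, or 4 and 1 adjusted over the list alone: VCAN, a proteoglycan (-2.35 ± 0.40), COL14A1 (-2.22 ± 0.34) and SFRP1, a Wnt antagonist (1.69 ± 0.31); the list's adjusted p was 0.01, and adjusted p = 0.377 with an estimated correlation. SYNM, an intermediate filament protein, was the 1 call among 15 smooth muscle genes (-1.88 ± 0.35), with 2 falls adjusted over the list alone. Camera for smooth muscle gave an adjusted p of 0.0259, and adjusted p = 0.377 with an estimated correlation. NPAS2 was the 1 rise among 12 clock genes (2.14 ± 0.35), or 3 adjusted over the list alone. Camera for clock genes gave an adjusted p of 0.0103, and adjusted p = 0.377 with an estimated correlation. The 28 ribosomal protein genes had a median of -0.31 (SD 0.20) and 0 calls either way. Camera for ribosomal proteins gave an adjusted p of 0.0393, and adjusted p = 0.759 with an estimated correlation. Among lipid genes, THRSP, a regulator of fat synthesis (2.70 ± 0.49), and ABCA1, a cholesterol exporter (1.99 ± 0.42), rose and ME1, malic enzyme (-1.41 ± 0.34), fell. NR0B2, a nuclear receptor that restrains bile acid synthesis, rose by 1.38 ± 0.29. Of 24 genes of xenobiotic and retinoid metabolism 3 fell and 0 rose, or 4 falls adjusted over the list alone, GSTT1 (-1.97 ± 0.31), GSTA3 (-1.93 ± 0.32) and CYP1A1 (-1.83 ± 0.47), while 14 differences were positive and camera's adjusted p was 0.934. Of 14 heterophil genes 3 fell and 0 rose over all genes and over the list alone, EXFABP (-2.31 ± 0.35), LYG2 (-2.03 ± 0.50) and PTX3 (-1.61 ± 0.38), while 7 differences were positive and camera's adjusted p was 0.326.

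On day 15, 1392 transcripts were higher and 1270 lower than on day 1, of which 151 and 187 had a symbol. The total of 2662 was 886, 918 and 414 without the product 1, product 2 and water arrays of day 1, it was 1320, 775 and 883 without those of day 15, and it rose to 4099 without the first product 1 array of day 7. Without the 3 product 1 arrays it was 1288.

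From day 7 to day 15 only 4 transcripts passed the threshold with limma, and each of them rose. Of all transcripts 0 fell past it, while 3651 (6.59%) had an unadjusted p under 0.05. The 1 with a symbol was HSPB9, which rose from 10.62 (SD 0.49, n = 3 samples) to 15.03 (SD 0.29, n = 3), by 4.41 ± 0.47 (adjusted p = 0.0127). Genes short of the threshold had CTLA4 at -1.79 ± 0.32, CD36 at 1.99 ± 0.36, CD72, a B cell receptor regulator, at -1.54 ± 0.32, EXFABP at -1.28 ± 0.35 and GZMA at -1.0 ± 0.38. The 32 proliferation genes had a median of -0.77 (SD 0.36) with 0 calls over all genes and 7 falls adjusted over the list alone; camera gave an adjusted p of 3.98e-17, and adjusted p = 0.642 with an estimated correlation. Camera also shifted down the T cell list (adjusted p 0.000454, 0 calls over all genes and 1 fall adjusted over the list alone), the cholesterol synthesis list (adjusted p 0.00583, 0 calls either way) and the red blood cell list (adjusted p 0.00583, 0 calls and 5 falls adjusted over the list alone); each had adjusted p = 0.642 with an estimated correlation. THRSP stood at 1.19 ± 0.49, short of the threshold. The count of 4 became 1 without the first array of product 2 on day 7, of water on day 7, of product 1 on day 15 or of water on day 15, and 2 without that of product 2 on day 15. The call of HSPB9 did not hold in every such fit. The count of 4 rose with all 15 arrays and the sample as a block, with a run block, and with trend and robust variance, as given under processing below. The fit takes day differences as alike in the treatments, so a change that differs between treatments enters its error.

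The comparison of the treatments over all days asks for differences that held on days 1, 7 and 15, with 3 samples a treatment. A treatment difference that changes between days enters the error of this fit. No transcript passed the threshold: limma gave 0 for product 1 against water, 0 for product 2 against water and 0 for product 1 against product 2, with 2297, 1490 and 1356 transcripts at an unadjusted p under 0.05. Those counts are 4.15%, 2.69% and 2.45% of transcripts, each below the share of 0.05 that this cut takes on average without any difference. FGF19, the ileal hormone that signals bile acid return to the liver, stood at 13.71 (SD 0.11, n = 3 samples) with product 1, 13.50 (SD 0.25, n = 3) with product 2 and 12.46 (SD 0.22, n = 3) with water. Its differences from water were 1.25 ± 0.24 and 1.04 ± 0.24, short of the threshold, and both share the water samples. CENPF differed from water by -1.59 ± 0.34 with product 1 and by -1.05 ± 0.34 with product 2, and SMC2, a condensin subunit, by -1.11 ± 0.31 and -0.77 ± 0.31. With product 1 against water, IL8L1, a chemokine that draws heterophils, stood at -1.29 ± 0.37, NFIL3, a clock-linked repressor, at 0.97 ± 0.30 and CYP2C18, a cytochrome P450, at 1.04 ± 0.32. With product 2 against water, the immediate early genes EGR1 and CYR61 stood at -1.0 ± 0.32 and -0.82 ± 0.27 and the chaperone gene DNAJA1 at 0.91 ± 0.39. The sign of the DNAJA1 difference held on only 2 of 3 days. Between the products, AvBD10 differed by 1.09 ± 0.43, XCR1 by 0.77 ± 0.30, TPH1, the enzyme that starts serotonin synthesis, by 0.64 ± 0.25, LYZ, a lysozyme, by 0.97 ± 0.44 and IL8L2, a chemokine, by -1.07 ± 0.42, none past the threshold. Only TPH1 of these kept its sign on all 3 days, while AvBD10, XCR1, LYZ and IL8L2 did so on 2 of 3.

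In the comparison over all days 28 of 32 proliferation genes were lower with product 1 than with water and 25 of 32 with product 2, with medians of -0.20 (SD 0.40) and -0.13 (SD 0.26), and both comparisons share the water samples. The days were not alike: the list's median after centring each gene was 0.16 with product 1 and 0.15 with water on day 7, and 0.65 with product 2 and 0.61 with water on day 1. Camera called the list for product 1 (adjusted p 0.000792, and adjusted p = 0.862 with an estimated correlation) and for product 2 (adjusted p 0.0373, and adjusted p = 0.936 with an estimated correlation), with 0 members called over all genes and 1 and 0 falls adjusted over the list alone. The immediate early list (14 genes, median -0.15) was called for product 2 at an adjusted p of 0.0373, and adjusted p = 0.936 with an estimated correlation, with 0 members called either way. On simulated data of this design, changes of 2 on the log2 scale were recovered in 54% of transcripts and changes of 1 in 2%.

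**Figure D2:**
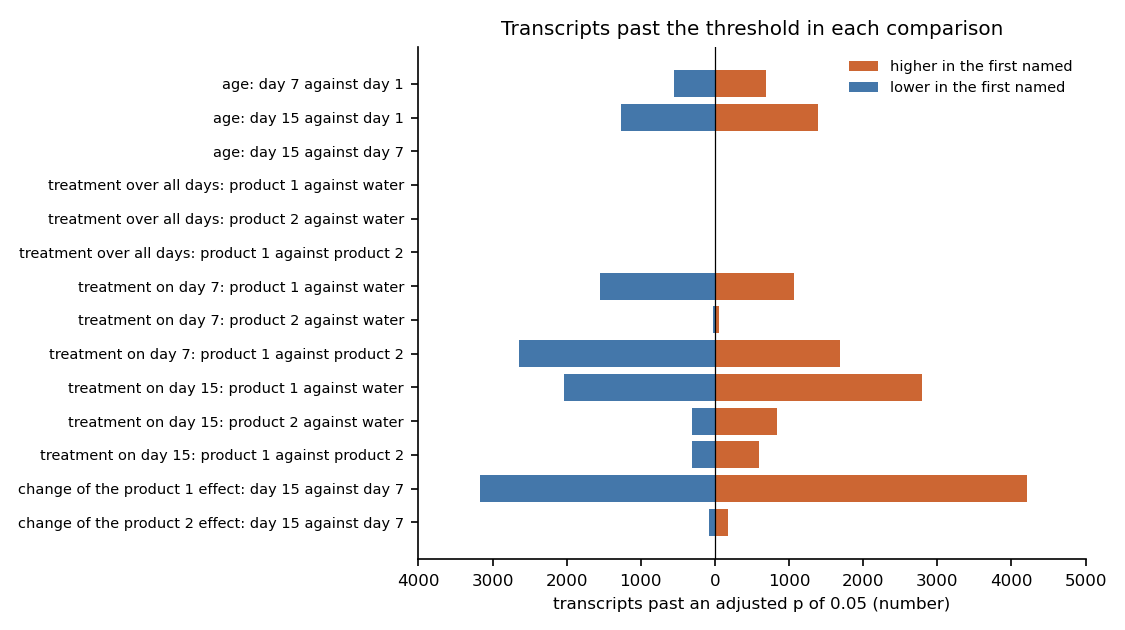
Number of transcripts past an adjusted p of 0.05 (horizontal axis) in each comparison (vertical axis). Bars to the right count those higher in the first named group and bars to the left those lower; the change of the product 1 difference between days 7 and 15 had 4210 and 3171.

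On day 7, ST6GALNAC1, an enzyme that adds sialic acid to mucin sugars, was higher with product 1 than with water, 9.79 (SD 0.21, n = 2 arrays) against 6.68 (SD 0.38, n = 2), a difference of 3.11 ± 0.25 (adjusted p = 0.00177). AvBD10 was higher by at least 2.28, since water lay at background. CYP1A1, a detoxifying cytochrome P450 (2.01 ± 0.23), MT3, a metallothionein (2.09 ± 0.22), TIMD4, a phagocyte receptor (1.93 ± 0.22), SST1, somatostatin (1.73 ± 0.19), and LYG2, a goose-type lysozyme (1.98 ± 0.25), were higher too. FGG, a fibrinogen chain, was lower, 9.27 (SD 0.01, n = 2) against 12.10 (SD 0.32, n = 2), as were ADAM33, a metalloprotease (-2.70 ± 0.23), DCTN1, a subunit of the dynein activator (-2.09 ± 0.24), and STAT3, a transcription factor of cytokine signalling (-1.63 ± 0.27).

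On day 7 named genes as a class had a median difference between product 1 and water of 0.09 on chromosomes 11 and up. It was 0.14 on the other chromosomes and 0.0166 over all transcripts, to be read beside the lists below. Enteroendocrine genes were higher with product 1 in 3 of 11 on day 7, or 4 adjusted over the list alone: SST1, the transcription factor ISL1 (0.96 ± 0.22) and RGS4, a regulator of G proteins (0.91 ± 0.22). The list had an adjusted p of 0.0136, and adjusted p = 0.197 with an estimated correlation. Crypt and stem cell genes were lower in 2 of 9 over all genes and over the list alone, SOX9 (-1.26 ± 0.21) and EPHB2 (-0.84 ± 0.19). Camera for crypt genes gave an adjusted p of 0.0173, and adjusted p = 0.197 with an estimated correlation. Oxidative phosphorylation genes were higher in 1 of 14, NDUFA5 (1.04 ± 0.19), a subunit of complex I, or 4 adjusted over the list alone, and the T cell list, with 0 of 21 calls either way, had a median of 0.42 (SD 0.50); both lists had an adjusted p of 0.0399, and adjusted p = 0.197 with an estimated correlation. The chemokines CCL20 (1.44 ± 0.19), CCL1 (1.33 ± 0.23) and CCL4 (1.11 ± 0.27) were higher and CX3CL1 was lower (-1.31 ± 0.19). FGF19 was higher by 1.13 ± 0.25. CPT1A, which admits fatty acids to mitochondria (-1.49 ± 0.19), ACACA, which starts fatty acid synthesis (-1.48 ± 0.29), EGR1 (-1.52 ± 0.25) and the clock gene PER2 (-1.11 ± 0.21) were lower.

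Product 1 was above water for 1064 transcripts and below it for 1555 on day 7, of which 158 and 116 had a symbol. The split went with the kind of transcript: 183 predicted transcripts were above water and 541 below, against 163 and 118 of those from RefSeq. That total of 2619 fell to 51 and 369 without the first and the repeat water array of day 7 and to 68 and 1079 without the first and the repeat product 1 array. It was 1383 without either product 1 array of day 15 and 1250 without either product 2 array of day 15. Of the 52 genes that the naming rule took, only ST6GALNAC1, AvBD10, FGG and ADAM33 kept their calls whichever array was left out.

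Product 2 on day 7 was above water for 51 transcripts and below it for 29, and 6 of them had a symbol. CBX1, a heterochromatin protein, was higher, 10.30 (SD 0.32, n = 2 arrays) against 7.98 (SD 0.18, n = 2), by 2.32 ± 0.34 (adjusted p = 0.0473). CCL4, a chemokine (1.83 ± 0.27), CYP1A1 (1.77 ± 0.23), DNMT3A, a DNA methyltransferase (1.56 ± 0.18), and CCDC50 (1.58 ± 0.21) were higher as well, and GSTA4, a glutathione transferase, was lower (-1.89 ± 0.25). There were 4 lists shifted without a member called over all genes. Proliferation had a median of -0.25 (SD 0.30, 32 genes, 2 falls adjusted over the list alone; adjusted p 0.000873, and adjusted p = 0.0876 with an estimated correlation) and extracellular matrix -0.18 (SD 0.47, 20 genes, 4 falls adjusted over the list alone; adjusted p 0.0018, and adjusted p = 0.0876 with an estimated correlation). The T cell list had a median of -0.21 (SD 0.24, 0 calls either way; adjusted p 0.0311, and adjusted p = 0.235 with an estimated correlation) and the endothelial list of 9 genes 0.46 (SD 0.33, 0 calls either way; adjusted p 0.0311, and adjusted p = 0.263 with an estimated correlation). The count of 80 dropped whichever of the 12 arrays of days 7 and 15 was left out. It was 32 without either product 1 array of day 7, 3 and 8 without the first and the repeat product 2 array and 3 and 4 without those of water, 14, 15 and 29 without either array of product 1, product 2 or water on day 15, and 18 with the run as a block. None of the 6 named calls held whichever array was left out. Trend and robust variance and the filters on dim transcripts raised the count of 80, as given under processing below.

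Product 1 and product 2 differed from each other on day 7 in 4323 transcripts, 1684 higher and 2639 lower with product 1. Predicted transcripts gave 345 and 945 of these and those from RefSeq 286 and 229. Of the 4110 transcripts with a symbol 281 were higher and 223 lower. Named genes had a median difference of 0.11 on chromosomes 11 and up and 0.19 on the others, against 0.0286 over all transcripts. The list counts and camera calls below are to be read beside these values. ST6GALNAC1 was 9.79 (SD 0.21, n = 2 arrays) with product 1 and 6.69 (SD 0.20, n = 2) with product 2, a difference of 3.10 ± 0.25 (adjusted p = 0.000869), and GSTA4 (1.92 ± 0.25) and the fatty acid carrier FABP4 (1.83 ± 0.22) were higher with product 1. CBX1 (-3.90 ± 0.34), FGG (-3.07 ± 0.21), ADAM33 (-2.79 ± 0.23), the transcription factors NFIC (-2.55 ± 0.29) and USF1 (-2.53 ± 0.28), IL8L2 (-2.46 ± 0.45) and SOX9 (-1.99 ± 0.21) were lower. T cell genes were higher in 4 of 21, or 7 adjusted over the list alone, with ICOS, a costimulatory receptor (1.66 ± 0.28), and CD3D, part of the T cell receptor complex (0.98 ± 0.21). Camera for T cells gave an adjusted p of 0.000667, and adjusted p = 0.121 with an estimated correlation. Proliferation genes were higher in 4 of 32, or 7 adjusted over the list alone, with DUT (1.26 ± 0.21), which keeps uracil out of DNA, and BIRC5, survivin (0.94 ± 0.20). Camera for proliferation gave an adjusted p of 0.00962, and adjusted p = 0.121 with an estimated correlation. Mucus, antimicrobial and barrier genes were higher in 7 of 25 over all genes and over the list alone, with LYZ (1.19 ± 0.24) and CLDN1, a tight junction protein (1.51 ± 0.32). Camera for barrier genes gave an adjusted p of 0.0233, and adjusted p = 0.131 with an estimated correlation. The enteroendocrine (2 of 11 higher, 4 adjusted over the list alone; adjusted p 0.0298), matrix (2 of 20 higher, 4 adjusted over the list alone; adjusted p 0.0298) and ribosomal (1 of 28 higher, 0 adjusted over the list alone; adjusted p 0.0425) lists each had adjusted p = 0.131 with an estimated correlation. The total was 1186 and 2543 without the first and the repeat product 1 array of day 7 and 880 and 2471 without those of product 2.

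On day 15, some chaperone genes were higher and some cell division genes lower with product 1 than with water, with the counts in the next paragraph. Not every chaperone gene went this way: HSPE1 (13.50 against 14.10) and HSPB1 (12.59 against 13.05) were lower with product 1. HSP90AA1, a major cytosolic chaperone, stood at 15.39 (SD 0.08, n = 2 arrays) against 12.89 (SD 0.07, n = 2), a difference of 2.49 ± 0.21 (adjusted p = 0.00187). The chaperone genes HSPA4L (1.86 ± 0.22), DNAJA1 (1.87 ± 0.28) and HSPA2 (1.48 ± 0.23), the HSP90 cochaperone gene CHORDC1 (2.25 ± 0.22), JMJD6, a hydroxylase (2.32 ± 0.22), and PER2 (1.76 ± 0.21) were higher. TMEM18 (-2.08 ± 0.20), the growth factor gene FGF18 (-2.08 ± 0.25), IL8L1 (-2.05 ± 0.21) and MT3 (-1.83 ± 0.22) were lower. FGF19 was higher by 1.36 ± 0.25.

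Named genes as a class had a median difference from water of -0.19 on chromosomes 11 and up and -0.15 on the others, against -0.015 over all transcripts. The list counts and camera calls below are to be read beside these values. Of 22 heat shock and unfolded protein genes 6 were higher and 0 lower with product 1 on day 15, or 8 adjusted over the list alone. Camera for heat shock genes gave an adjusted p of 0.000684, and adjusted p = 0.0641 with an estimated correlation. Of 32 proliferation genes 9 were lower and 0 higher, or 13 adjusted over the list alone, among them SMC2 (-1.27 ± 0.25), KIF23, a kinesin of cell division (-1.26 ± 0.22), and FEN1, a replication nuclease (-1.10 ± 0.19). Their median was -0.57 (SD 0.38) and the list's adjusted p was 3.3e-08; this was the only list call of any comparison that held with an estimated correlation (adjusted p = 0.0133 with an estimated correlation). Ribosomal protein genes had a median of -0.27 (SD 0.23, 28 genes, 1 lower, 0 adjusted over the list alone; adjusted p 0.00503, and adjusted p = 0.0796 with an estimated correlation). Liver secreted proteins were lower in 2 of 10, FGG (-1.47 ± 0.21) and the thyroid hormone carrier TTR (-1.16 ± 0.22), or 3 adjusted over the list alone. Camera for liver proteins gave an adjusted p of 0.00856, and adjusted p = 0.121 with an estimated correlation. The immediate early list had 1 higher member, FOSL2 (1.07 ± 0.23), and 2 lower, CCN2 (-0.97 ± 0.24) and DUSP4 (-0.75 ± 0.19), of 14, with 1 and 6 adjusted over the list alone. Camera for immediate early genes gave an adjusted p of 0.00856, and adjusted p = 0.139 with an estimated correlation. Matrix genes were higher in 3 of 20, or 4 adjusted over the list alone, led by PDGFRA, a growth factor receptor of fibroblasts (1.52 ± 0.21). Camera for matrix genes gave an adjusted p of 0.0299, and adjusted p = 0.139 with an estimated correlation. T cell genes were lower in 3 of 21 and higher in 1, or 5 and 1 adjusted over the list alone, with XCL1 (-1.38 ± 0.23) and CD8A (-0.91 ± 0.21) lower. B cell genes were lower in 3 of 19 and higher in 1, or 4 and 1 adjusted over the list alone, with BTK, a kinase of B cell signalling (-1.47 ± 0.24), and CD79B, part of the B cell receptor (-1.14 ± 0.24), lower. Macrophage genes were higher in 2 of 12 and lower in 1 over all genes and over the list alone, with the scavenger receptor gene MARCO higher (1.44 ± 0.20). Camera called none of these 3 lists, with adjusted p values of 0.0812, 0.358 and 0.925.

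Product 1 was above water for 2798 transcripts and below it for 2037 on day 15, a share of 57.9% above that became 47.7% (2138 above and 2340 below) when arrays were centred on their median only. The split also went with the kind of transcript: 1263 predicted transcripts were above water and 629 below, against 189 and 279 of those from RefSeq. Of the 4110 transcripts with a symbol 187 were above and 275 below. The total of 4835 was 511 and 546 without the first and the repeat product 1 array of day 15, 2577 and 1524 without those of water, and 3216 without either product 2 array of day 15. Of the 72 genes that the naming rule took as called, 13 kept their calls whichever array was left out. Among them were HSP90AA1, HSPA4L, CHORDC1, JMJD6, PER2, TMEM18, FGF18, IL8L1 and MT3.

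Product 2 on day 15 shared its water arrays with that comparison and was again above water for some chaperone genes. DNAJA1 stood at 13.09 (SD 0.21, n = 2 arrays) against 10.94 (SD 0.45, n = 2), a difference of 2.15 ± 0.28 (adjusted p = 0.00908), HSP90AA1 differed by 1.78 ± 0.21, HSPA4L by 1.46 ± 0.22 and HSPA2 by 1.40 ± 0.23. CD200R1B, an inhibitory receptor of immune cells, was higher by at least 1.95, SLC9A9, an endosomal ion exchanger, by 2.33 ± 0.21, and GZMA by 1.33 ± 0.21. AREG, a ligand of the epidermal growth factor receptor, was lower, 7.89 (SD 0.17, n = 2) against 9.99 (SD 0.10, n = 2), as were SQLE (-1.46 ± 0.20) of cholesterol synthesis, IL8RB, a chemokine receptor of heterophils (-1.63 ± 0.29), and FOS (-1.20 ± 0.24). Of 22 heat shock genes 4 were higher, or 7 adjusted over the list alone. Camera for heat shock genes gave an adjusted p of 3.08e-05, and adjusted p = 0.0524 with an estimated correlation. Of 11 cholesterol synthesis genes 2 were lower, or 3 adjusted over the list alone. Camera for cholesterol synthesis gave an adjusted p of 0.000977, and adjusted p = 0.0811 with an estimated correlation. Clock genes were higher in 2 of 12, NFIL3 (1.30 ± 0.24) and PER2 (1.09 ± 0.21), or 3 adjusted over the list alone. Camera for clock genes gave an adjusted p of 0.0359, and adjusted p = 0.182 with an estimated correlation. Heterophil genes were lower in 1 of 14 over all genes and over the list alone (adjusted p 0.0179, and adjusted p = 0.137 with an estimated correlation) and immediate early genes in 1 of 14, or 5 adjusted over the list alone. Camera for immediate early genes gave an adjusted p of 0.0256, and adjusted p = 0.21 with an estimated correlation. Proliferation had a median of -0.29 (SD 0.39) with 0 calls over all genes and 5 lower and 1 higher adjusted over the list alone. Camera for proliferation gave an adjusted p of 0.00646, and adjusted p = 0.0811 with an estimated correlation.

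Product 2 was above water for 838 transcripts and below it for 312 on day 15, of which 56 and 25 had a symbol. That total of 1150 was 15 and 18 without the first and the repeat product 2 array of day 15, 709 and 141 without those of water, 533 without either product 1 array of day 15 and 743 without either water array of day 7. Of the 34 genes that the naming rule took as called, 0 kept their calls in every fit with 1 array left out.

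**Figure D3:**
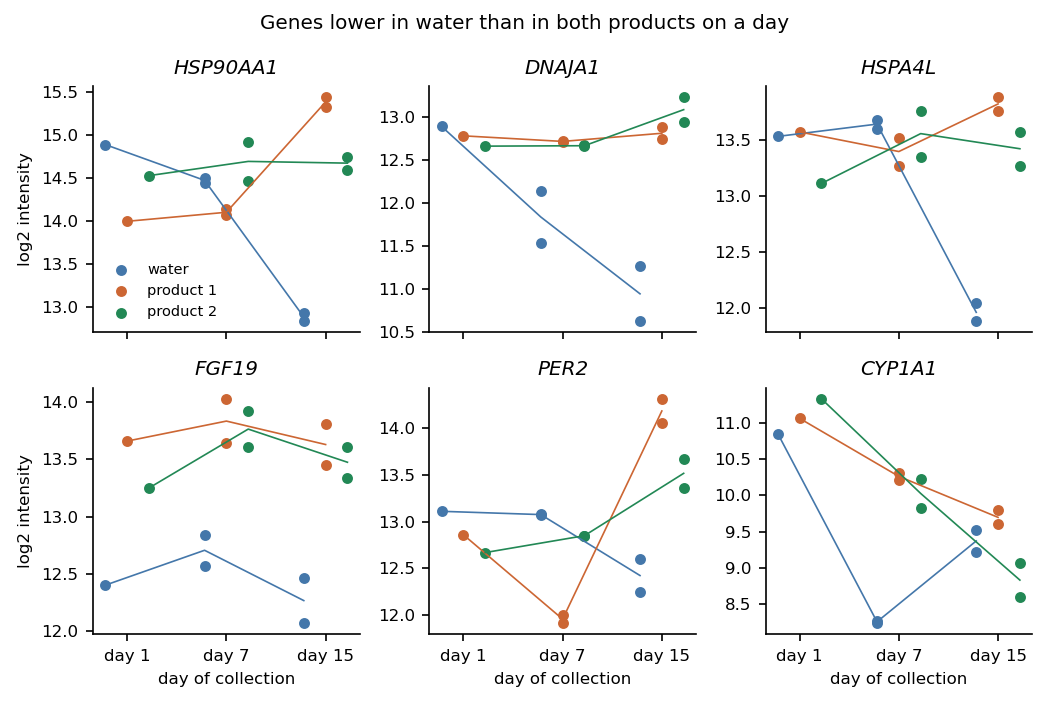
Log2 intensity (vertical axis) of 6 genes by day (horizontal axis), with each point 1 array, colours for the treatments and lines joining sample means. HSP90AA1, DNAJA1 and HSPA4L were lowest in the water sample of day 15, FGF19 was lower in water than in both products on days 1, 7 and 15 and CYP1A1 lower in water on day 7.

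Between the products on day 15, 598 transcripts were higher and 311 lower with product 1, of which 50 and 48 had a symbol. RARA, a retinoic acid receptor, stood at 13.47 (SD 0.02, n = 2 arrays) with product 1 and 11.53 (SD 0.20, n = 2) with product 2, a difference of 1.94 ± 0.25 (adjusted p = 0.0165). DCTN1 (1.93 ± 0.24), ADAM33 (1.82 ± 0.23), STIM1, a calcium sensor (1.80 ± 0.23), and IHH, a hedgehog ligand of the gut epithelium (1.73 ± 0.23), were higher with product 1. TMEM18 (-1.82 ± 0.20), FGG (-1.76 ± 0.21), MT3 (-1.69 ± 0.22), THRSP (-1.58 ± 0.24) and POU2AF1 (-1.47 ± 0.27) were lower. Camera shifted 10 lists. Named genes as a class had a median difference of -0.09 on chromosomes 11 and up and -0.19 on the others, against -0.0193 over all transcripts. The proliferation (median -0.36, SD 0.38, 0 of 32 calls, 3 lower adjusted over the list alone; adjusted p 0.000319) and ribosomal lists (median -0.26, SD 0.18, 0 calls either way; adjusted p 0.00145) each had adjusted p = 0.0706 with an estimated correlation. The T cell list (median -0.36, 0 of 21 calls, 1 higher and 2 lower adjusted over the list alone; adjusted p 0.00369) and the liver list (1 of 10 lower, 2 adjusted over the list alone; adjusted p 0.00369) each had adjusted p = 0.0897 with an estimated correlation. The interferon (median -0.37, 0 of 12 calls, 4 lower adjusted over the list alone; adjusted p 0.00226), B cell (1 of 19 lower, 2 higher and 3 lower adjusted over the list alone; adjusted p 0.0378), crypt (median 0.27, 0 of 9 calls, 3 higher adjusted over the list alone; adjusted p 0.0393) and smooth muscle (median 0.25, 0 of 15 calls, 1 higher adjusted over the list alone; adjusted p 0.0393) lists each had adjusted p = 0.242 with an estimated correlation. The cytokine list (1 of 29 lower, 2 adjusted over the list alone; adjusted p 0.0378) had adjusted p = 0.148 with an estimated correlation and the enteric neuron list (0 of 19 calls, 1 lower adjusted over the list alone; adjusted p 0.0393) had adjusted p = 0.177 with an estimated correlation. The total of 909 fell to 0 without either product 1 array or the repeat product 2 array of day 15 and to 2 without the first product 2 array. It was 440, 574 and 444 without either array of product 1, product 2 or water on day 7, 465 without either water array of day 15, 435 with median centring and 509 with the run as a block. None of the 25 named calls held in every fit with 1 array left out. The count of 909 rose with trend and robust variance and with the filters on dim transcripts, as given under processing below.

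The difference between product 1 and water itself changed between day 7 and day 15. This interaction passed the threshold for 7381 transcripts, 4210 with a more positive difference on day 15 and 3171 with a more negative one. ADAM33 went from -2.70 ± 0.23 on day 7 to a change of 4.06 ± 0.33 by day 15 (adjusted p = 0.0013; n = 2 arrays a group), DCTN1 changed by 3.56 ± 0.34, RARA by 3.14 ± 0.35, PER2 by 2.87 ± 0.30 and HSP90AA1 by 2.86 ± 0.29. MT3, at 2.09 ± 0.22 on day 7, changed by -3.91 ± 0.31, KK34, an interleukin-like gene, by -3.33 ± 0.27, TMEM18 by -3.15 ± 0.29 and SST1 by -2.62 ± 0.27. Predicted transcripts were more often among the positive changes (1774 against 697) and RefSeq transcripts among the negative ones (272 against 523). The share of transcripts above 2 times the random-probe value moved as well: on day 7 it was 54.7% and 56.0% on the product 1 arrays and 57.6% and 58.0% on those of water, and on day 15 it was 60.6% and 60.1% against 57.9% and 55.1%. The total was 4236 and 4653 without the first product 1 and the first water array of day 7 and 4093 and 4071 without the first and the repeat product 1 array of day 15.

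The difference between product 2 and water changed in 268 transcripts, 181 positive and 87 negative, of which 16 and 9 had a symbol. POSTN, a matrix protein, changed by 2.03 ± 0.27 (adjusted p = 0.0236; n = 2 arrays a group) and MX1 by 1.95 ± 0.32, while CCL4 changed by -2.83 ± 0.38, CYP1A1 by -2.31 ± 0.33 and DNMT3A by -1.72 ± 0.26. The count of 268 was 125 without either product 1 array of day 7, 7 and 22 without the first and the repeat product 2 array and 8 and 11 without those of water. It was 54 without either product 1 array of day 15, 9 and 8 without the first and the repeat product 2 array, 98 and 25 without those of water, and 99 with the run as a block. The 19 named calls included 0 that held whichever array was left out. With trend and robust variance, a slide block or the filters on dim transcripts the count of 268 rose, as given under processing below.

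**Figure D4:**
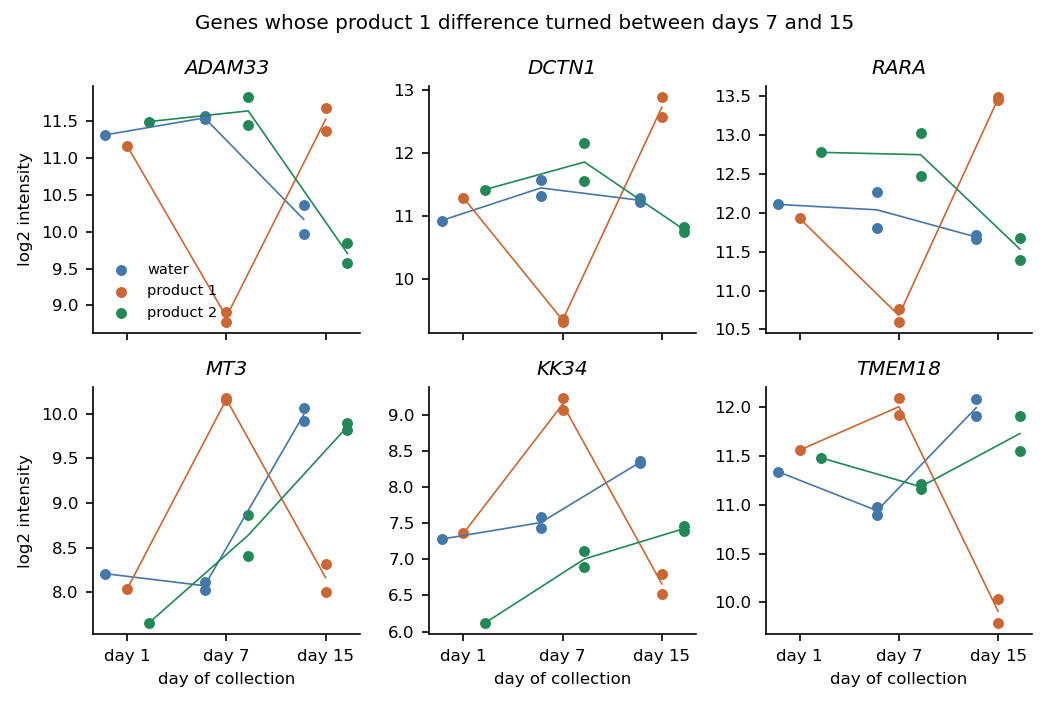
Log2 intensity (vertical axis) of 6 genes by day (horizontal axis), with each point 1 array, colours for the treatments and lines joining sample means. ADAM33, DCTN1 and RARA were lower with product 1 than with water on day 7 and higher on day 15, and MT3, KK34 and TMEM18 went the other way.

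Day 1 had 1 array a treatment, so its differences carry no test. ALDH1A1, a retinal dehydrogenase, stood at 12.81 with product 1 and 9.75 with water, and the complement gene C3 at 9.50 and 7.06, with 9.36 for product 2. CENPF stood at 10.34 with product 1, 10.81 with product 2 and 12.91 with water. Cholesterol synthesis genes had a median difference between product 1 and water of 0.95, with 5 of 11 at least 1 higher, among them INSIG1, a sterol sensor partner (1.46), and SQLE (1.16). On day 1 between 5273 and 6025 transcripts differed at least 2-fold between any pair of treatments, while between 2633 and 6583 did so between the 2 arrays of a single sample on days 7 and 15.

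**Figure D5:**
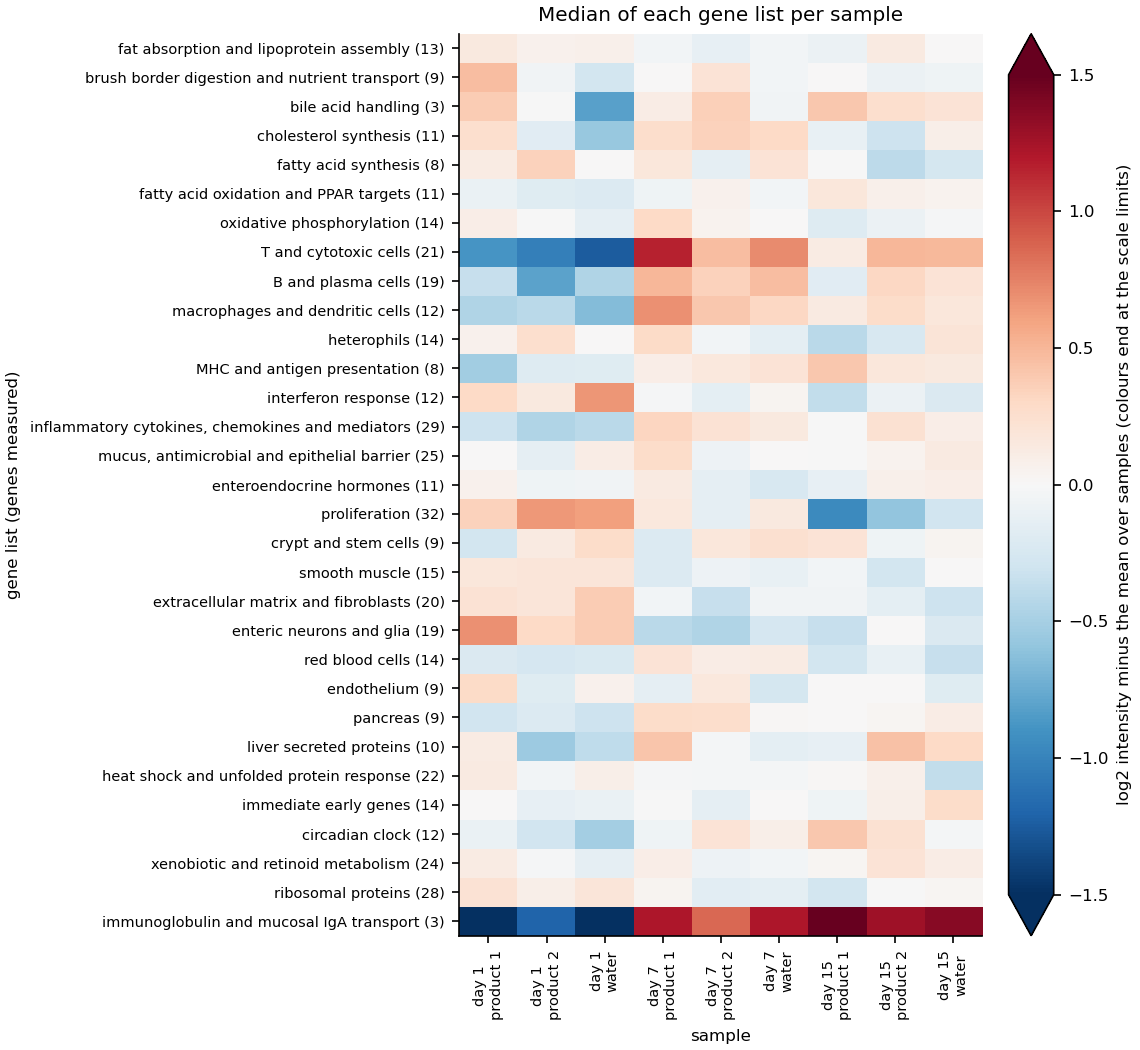
Median log2 intensity of each gene list (vertical axis, with the number of genes measured) in each of the 9 samples (horizontal axis), as colour, after subtracting each gene's mean over the samples. The T and cytotoxic cell list went from -0.88, -1.03 and -1.25 on day 1 to 1.16, 0.46 and 0.71 on day 7 (product 1, product 2, water), and the proliferation list stood at -0.96, -0.59 and -0.29 on day 15.

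The positions below come from the array's own annotation, whose genome build is not given in the sources used here. JCHAIN lay on chromosome 4 from 51507274 to 51513039 with 4 exons, PIGR on chromosome 26 from 2390696 to 2401255, GZMA on chromosome Z from 15998582 to 16002776 and AvBD10 on chromosome 3 from 110227858 to 110230473. HSP90AA1 lay on chromosome 5 from 51983679 to 51988436, FGF19 on chromosome 5 from 18743574 to 18748511, ADAM33 on chromosome 4 from 93121723 to 93145342 and MT3 on chromosome 11 from 2102931 to 2103780.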

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

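The tests of run and slide for the product 1 change and for the heat shock genes, of the number of samples, of the water sample of day 15, and of both explanations for the immune genes were chosen only after the result was seen.

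The difference between product 1 and water was not the same on day 7 and day 15 for 7381 transcripts by limma's interaction test. The largest positive changes among genes with a symbol were those of ADAM33 (4.06), DCTN1 (3.56), ASIC1, an acid-sensing ion channel (3.20), RARA (3.14), CD200R1B (2.92), PLN, a regulator of calcium pumps (2.92), PIK3CA, a lipid kinase subunit (2.88), PER2 (2.87), HSP90AA1 (2.86) and THRB, a thyroid hormone receptor (2.86). The largest negative ones were those of MT3 (-3.91), KK34 (-3.33), TMEM18 (-3.15), SPATA4 (-2.83), CFC1 (-2.83), RBP (-2.82), BETA3 (-2.77), MRPS30 (-2.77), FSHR (-2.74) and CHRNA6 (-2.68). For CD200R1B, BETA3 and CHRNA6 at least 1 of the 4 groups lay at background on both arrays, and for PLN and THRB water on day 15 did on 1 of 2 arrays, so the sizes and ranks of these 5 are uncertain.

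Of the 4110 transcripts with a symbol, 267 changed more positively and 512 more negatively past the threshold. Named genes thus shifted down as a class, and camera, run against all transcripts, does not correct for that. By list, camera put the change of the product 1 difference down for proliferation (adjusted p 0.000196, and adjusted p = 0.0644 with an estimated correlation). In that list 8 of 32 genes were more negative, or 11 more negative and 1 more positive adjusted over the list alone. Ribosomal proteins (0 of 28 either way; adjusted p 0.00396) had adjusted p = 0.0963 with an estimated correlation. Heterophil genes (2 of 14 negative, 5 adjusted over the list alone; adjusted p 0.0146), T cell genes (7 of 21 negative and 1 positive, 10 and 3 adjusted over the list alone; adjusted p 0.0229) and oxidative phosphorylation (4 of 14 negative over all genes and over the list alone; adjusted p 0.0229) each had adjusted p = 0.12 with an estimated correlation. Enteroendocrine genes (3 of 11 negative, 5 adjusted over the list alone; adjusted p 0.0248) had adjusted p = 0.128 with an estimated correlation. The positive changes were in heat shock genes (4 of 22 positive and 1 negative, the same counts adjusted over the list alone; adjusted p 0.0229, and adjusted p = 0.12 with an estimated correlation), crypt genes (3 of 9 over all genes and over the list alone; adjusted p 0.0248, and adjusted p = 0.14 with an estimated correlation) and clock genes (2 of 12, 3 adjusted over the list alone; adjusted p 0.033, and adjusted p = 0.133 with an estimated correlation).

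For the change of the product 1 difference, a signal-dependent bias left by quantile normalization but removed by cyclic loess is argued against. Under cyclic loess 93.8% of the calls (6926 of 7381) stayed past the threshold with their sign. Both methods adjust arrays by intensity, so a bias that both leave stays open. The median change of named genes was -0.28 on chromosomes 11 and up and -0.29 on the others, against -0.0432 over all transcripts. For the 5341 calls with a mean log2 over 8, a run or slide batch is argued against by the change in the first-run arrays and in the repeat-run arrays on other slides, which correlated at 0.867 over all 19294 such transcripts, although genes are not independent replicates. For the 2040 dimmer calls it stays open: that correlation was 0.291 over the other 36071 transcripts, where noise also lowers it, and 0.493 over all. Base composition stays open: the share of called genes on chromosomes 11 and up was 33.9% among positive and 29.8% among negative changes, a ratio of 1.14 whose interval, 0.86 to 1.47, passes the bound set for excluding it. A difference between individual samples also stays open, since there was 1 sample per treatment and day, and the treatment cannot be told apart from the sample.

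The difference between product 2 and water changed between the days for 268 transcripts. The positive changes of named genes were those of CD200R1B (2.76), TUBA8B (2.49), ACTC1, a cardiac actin (2.27), GYPC, a red cell membrane protein (2.26), LCORL (2.19), SLC9A9 (2.14), POSTN (2.03), TRMT6 (2.01), GPRIN2 (1.96) and MX1 (1.95). The negative ones were CCL4 (-2.83), CCDC50 (-2.41), CYP1A1 (-2.31), USP2 (-2.10), NPVF (-2.0), SRSF5, a splicing factor (-1.80), IL8L1 (-1.72), DNMT3A (-1.72) and SEC16B (-1.60). The sizes of CD200R1B and NPVF are uncertain, since water on day 15 lay at background for the first and 3 of the 4 groups did for the second, and TUBA8B was at background on 1 of the 2 arrays of water on day 15. Camera called cholesterol synthesis down (0 of 11 over all genes, 3 negative adjusted over the list alone; adjusted p 0.0186, and adjusted p = 0.175 with an estimated correlation). It called matrix genes up (1 of 20, 5 adjusted over the list alone; adjusted p 0.00335) and heat shock genes up (0 of 22, 2 adjusted over the list alone; adjusted p 0.00104), each with adjusted p = 0.106 with an estimated correlation.

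On day 15, 6 of 22 heat shock genes were called lower in water than with product 1 (8 adjusted over the list alone; camera adjusted p 0.000684, and adjusted p = 0.0641 with an estimated correlation) and 4 of 22 than with product 2 (7 adjusted over the list alone; camera adjusted p 3.08e-05, and adjusted p = 0.0524 with an estimated correlation). Not all members went this way: water stood above both products for ATF4 (14.16 against 14.01 and 13.94), HSPE1 (14.10 against 13.50 and 13.86) and HSPB1 (13.05 against 12.59 and 12.95). For a run or slide batch, all 22 measured genes of the list were compared between runs, called or not. Their differences from water in the first and the repeat run correlated at 0.938 for product 1 and 0.855 for product 2. The 95% interval of the latter was 0.678 to 0.938, with genes taken as independent. In each run 18 of 22 were above water for each product. The differences thus repeated between runs, but the set includes the called genes, whose calls need both runs to agree. A correlation also cannot see a shift shared by the whole list, so a run or slide batch stays open. The run medians themselves were less alike, 0.25 and 0.44 for product 1 and 0.40 and 0.41 for product 2, so the smaller was 0.57 of the larger for product 1. A ratio planned for the called genes is not used, since a call needs both runs to agree. Whether the water sample of day 15 stands apart stays open: it was the lowest of the 9 samples for 11 of the 22 genes (50%), between the bounds set. HSP90AA1 stood at 12.89 in that sample and between 14.0 and 14.89 on days 1 and 7, but also reached 15.39 with product 1 on day 15. HSPA2 stood at 15.12 and 15.04 with the products on day 15, against 13.85 to 13.96 with them earlier, and at 13.64 in water. Low water values were not confined to that day: on day 7 water stood at 12.91 for HSPA2 and at 11.84 for DNAJA1, below both products. The treatment itself stays open, as untested, since there was 1 water sample that day.

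Of the T cell, B cell and macrophage genes, 15 of 21, 6 of 19 and 4 of 12 were called higher on day 7 than on day 1. On day 15 these were 12, 5 and 3, and 0 of 14 heterophil genes were called higher on either day. With an estimated correlation camera held none of the first 3 lists (adjusted p 0.0561 to 0.143). The contrast with heterophil genes was not tested. A lower share of other tissue layers as the whole cause would raise epithelial genes alike. It is argued against, if brush border genes were otherwise steady, by the T cell list's median on day 7. That median lay 2.12 above that of the brush border list (SDs across genes 0.89 and 0.45). As a part of the cause it stays open: 17 of 19 enteric neuron and glia genes, 16 of 20 matrix genes and 12 of 15 smooth muscle genes had negative differences on day 7. For blood left in the tissue, the called T cell genes kept a median share of 0.82 of their day 7 change on day 15 (15 genes). The called red cell genes kept 0.12 (4 genes), a difference of 0.70. Over the whole lists the medians of day 15 against day 1 were 1.40 and -0.01, so red cell genes did not stay up with T cell genes. Blood still stays open: both called sets were picked by their day 7 change, the red cell set is small, and red cell genes gauge white cells of the blood only indirectly. Age and time since inoculation stay open, as untested, because the design gives them as 1 variable.

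For groups of 3 samples, 10 splits are too few for a share under 0.05. For days 7 and 1, days 15 and 1 and days 15 and 7, the real counts were 1238, 2662 and 4, each with 0 as the highest of the other splits, so 1 of 10 splits gave as many. For product 1 against water over all days the real count was 0 and the highest other 1, and for the other 2 comparisons both were 0, so 10 of 10 gave as many.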

How the results depend on the processing

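Cyclic loess, the block mean, the filter at 2 times the random-probe value, the fits without product 1, and list tests with a run block or a left-out array were chosen after seeing the data; the cause of a moved count was not tested unless fewer samples or transcripts show it. No named gene changed direction in any alternative. The numbers do not pair the arrays: pairing correlations ran from -0.114 to 0.148 over all transcripts and from -0.263 to 0.36 over those with a mean log2 over 8.

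With all 15 arrays and the sample as a random block the day 7 against day 1, day 15 against day 1 and day 15 against day 7 counts (1238, 2662, 4) were 3831, 6694 and 287, and with a run block 2996, 5536 and 152. With repeat arrays averaged the first 2 were 2206 and 4617, with a slide block the first was 2076, and without product 1 they were 760 and 1288; trend and robust variance made the last 21. Trend and robust variance gave 6132, 1322 and 7881 on day 7 (product 1 and 2 against water, and between products; reported 2619, 80, 4323), 8258, 3031 and 3937 on day 15 (reported 4835, 1150, 909), and 2307 for the change of product 2 (reported 268). Dropping the dimmest transcripts by mean gave 4128, 234, 1797, 1948 and 674 for product 1 and product 2 on day 7, product 2 and between products on day 15, and the product 2 change, and the filter at 2 times the random-probe value 4185, 241, 1877, 1975 and 748. Median centring gave 33, 435 and 155, and the run block 18, 509 and 99, for product 2 on day 7, between products on day 15 and the product 2 change; a slide block gave 2038 for product 2 on day 15 and 1088 for its change. Median centring moved the median of all transcripts by 0.122 (between products, day 7), -0.117 and -0.118 (product 1 and 2, day 15) and -0.161 (product 1 change). The product 1 change count (7381) stayed between 6975 and 10655 in these alternatives, and over all days treatments stayed at 0 in each.

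Leaving out 1 array, a lone array being assumed to vary like the other groups, gave 174 to 1461, 414 to 4099 and 1 to 4 for the days in the above order, 0 to 0 for treatments over all days, 51 to 2129, 3 to 32 and 880 to 3976 on day 7, 511 to 4377, 15 to 942 and 0 to 574 on day 15, and 4071 to 7031 and 7 to 125 for the changes. Of 475 named calls, 130 held in every such fit. List calls numbered 30 for days, 3 over all days and 48 on days 7 and 15; an estimated correlation left 0, 0 and 1, and fry gave 14, 0 and 104. Leaving out 1 array or sample gave 25 to 33, 1 to 9 and 41 to 49; over all days it was 5, 6, 1, 9, 8 and 5 without day 1 product 1, day 1 water, day 7 water, day 15 product 1, product 2 and water. Named calls lost numbered 68 with the run block, 64 with median centring, 48 with a 2-fold minimum, 33 as deposited and 14 with cyclic loess. Between 54.7% and 61.5% of transcripts on an array lay above 2 times its random-probe value, so dim transcripts limit what can be seen.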

Other observations

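The lists of nutrient handling were called by camera in none of the comparisons. On day 7 against day 1, fat absorption had a median of -0.21 (SD 0.75, 13 genes; adjusted p 0.411, 1 fall, and 1 rise and 1 fall adjusted over the list alone), brush border digestion and transport -0.19 (SD 0.45, 9 genes; adjusted p 0.525, 0 calls either way) and bile acid handling 0.39 (SD 0.80, 3 genes; adjusted p 0.352, 0 calls and 1 rise adjusted over the list alone). Fatty acid synthesis had a median of -0.01 (SD 1.00, 8 genes; adjusted p 0.562, 0 calls, and 3 rises and 1 fall adjusted over the list alone), fatty acid oxidation 0.42 (SD 0.28, 11 genes; adjusted p 0.0879, 0 calls either way) and xenobiotic and retinoid metabolism 0.12 (SD 0.68, 24 genes; adjusted p 0.449, 1 fall, 2 adjusted over the list alone).

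On day 1, where no test was possible with 1 array a treatment, the interferon response list had a median difference from water of -0.28 with product 1 and -0.56 with product 2, and the cholesterol synthesis list 0.95 and 0.47. IFNW1, an interferon, stood at 7.77 with product 1, 7.43 with product 2 and 9.89 with water, EIF2AK2, an antiviral kinase, at 13.16, 12.05 and 13.18, and SMC2 at 11.40, 11.61 and 13.06. EEF1A1, a translation elongation factor, stood at 11.92 with product 1, 8.72 with product 2 and 8.94 with water.

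The first 2 principal components of all transcripts held 40.4% and 19.1% of the variance. On the second, the product 1 arrays stood at -62.3 and -60.3 on day 7 and at 45.6 and 44.6 on day 15, and the day 7 and day 15 arrays of the other treatments between -16.9 and 15.7. Each array of days 7 and 15 had the other array of its sample as its nearest, with rank correlations across transcripts of 0.983 to 0.992.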
